A study of Mus musculus with 71 samples.

How the data were processed

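RNA was measured in 71 libraries from 19 female mice aged 6 months: 5 WT mice given saline, 6 5xFAD mice given saline and 8 5xFAD mice given 2E. The sample labels name each library's animal, group and brain region, and groups were taken from these labels. The labels' cohort text gives 10 WT, 9 saline-treated 5xFAD and 8 2E-treated animals, so part of the cohort has no library here. Per the labels' protocols, RNA came from 14 µm frozen sections of fixed tissue and libraries were made with SmartSeq2 after selection for polyadenylated RNA, without molecular identifiers.

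The deposited values are counts per gene, whole numbers that were not normalized. Per the submitters' processing notes, the authors used bcl2fastq, FastQC, Trim Galore and STAR against GRCm38 to make these counts. Their versions, the counting tool, the annotation and any filter on genes are not given in the sources used here. The table holds 15860 mouse genes, and 71 of its sample columns were used. It also holds 1 entry for GFP, which is not a mouse gene, with 2 to 28 counts per library (median 11, 0.000541% of all counts). It was kept out of library sizes and tests. Of the genes on the lists below, 47 are absent from the table. Coordinates are from GENCODE vM21 on GRCm38, in which 140 of 140 genes given by the naming rule have 1 locus. Reads cannot be divided between overlapping or near-identical genes in these counts. When naming genes, 2, 5 and 2 called genes without a gene symbol or of pseudogene type were passed over for disease, 2E and 2E against WT.

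Library totals ran from 449934 to 3842419 counts, with medians of 2307521 in cortex, 2024893 in hippocampus, 2601096 in hippocampus with cortex and 2103557 in brain stem. Over regions the means were 2020783 (SD 848038) for WT, 1974639 (SD 894177) for saline-treated 5xFAD and 2499648 (SD 419578) for 2E. The floor was 3 counts per library. Fitted changes of genes near it depend on the prior count: Adora2a, Ccl6, Cst7, Dcn, Dlk1, Ifit3, Syndig1l and Tlr2 had a median of at most 3 counts in some group, and Adora2a 0 counts in every WT hippocampus library. Pairs of libraries within a group were compared with counting noise: over 189 pairs the chi-square per degree of freedom was 3.62 to 44.9, and 0 pairs were identical.

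Within each region, edgeR 4.0.16 (R 4.3.3) was run with TMM normalization, filterByExpr with a minimum count of 10, a robust quasi-likelihood fit of all 3 groups and Benjamini-Hochberg adjustment. Over regions, limma 3.58.1 with voom was run on 12 region and group means, with the animal as a random block (estimated correlation 0.0402) and the mean of the 4 regional contrasts tested. Regions were compared in edgeR with the animal as a fixed block, and the difference of an effect between brain stem and cortex as an interaction, in a second fit of this kind with its own filter on low counts (11655 and 14586 genes). Genes passed at an adjusted p under 0.05. SE values are those of the fits. Gene lists with at least 5 tested members (32 of 33 lists) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. List scores, given as mean log2 CPM of the members, were averaged per animal after adjustment for region and tested by exact permutation of the animals. Each list was also adjusted over its own members alone.

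The genes named for disease and for 2E over regions are the 12 that rose and the 12 that fell with the smallest p among those past the threshold, and in each region the 5 on either side. For each gene list up to 4 members past the threshold are named, and Thy1 and App in comparisons of genotype. Some genes that this rule gives are not reported here, and the sensitivity counts of named genes leave them out. The disease genes found are followed in the other comparisons. The number of libraries showing a direction counts those above or below the mean of the reference group in their region. Over regions, libraries of the same animal are not independent, so these are not counts of replicates. The comparisons, tests, gene lists and naming rule were chosen before the data were examined.

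How far disease genes moved with 2E was measured as the slope through the origin of the 2E change on the disease change, with the saline-treated 5xFAD animals divided into 2 disjoint sets, averaged over 20 divisions. Because both changes share saline animals, the 14 transgenic animals were also regrouped at random 100 times and slope, covariance and correlation were computed again.

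Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, only the 2 groups compared, a replicate block, covariates for plate position and genes detected, voom with quality weights, 1 value per animal, and leaving out shallow libraries, libraries at unusual plate positions, the brain stem or each library or animal in turn. Plate positions were read from a code in the column names, whose meaning the sources used here do not give. Shallow libraries were those with totals or genes detected under a fixed share of the median of their region. Alternatives chosen after seeing the data were exact tests with each animal left out, the fit without the cortex and hippocampus libraries of 2E replicate 8, the striatum score as a covariate, lists without shared members, and slopes over genes chosen otherwise. Up to 100 other splits of the animals or libraries were tested for the gene counts by edgeR and limma and the camera counts of lists in disease and with 2E. The main edgeR and limma fits, camera at the preset correlation and the slope were tested on simulated data with known changes, drawn from the real means and library sizes. DESeq2, the other alternatives, camera at an estimated correlation, fry and the exact tests were not. For 4-fold changes recovery was 61.0% in the disease comparison over regions, 74.2% in the 2E comparison over regions, 62.9% for 2E against WT over regions, 33.3% in the cortex disease comparison, 74.5% in hippocampus against cortex and 84.6% in brain stem against cortex. For 2-fold changes it was 36.5%, 52.3%, 46.2%, 14.0%, 55.8% and 52.7%. Over 200 changed genes a slope of -0.5 was recovered as -0.46 and a slope of 0 as 0. These were the genes known to be changed, and the simulated libraries carried no animal effect. Bias from choosing the genes with the same saline animals was therefore not tested there.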

Results

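The libraries come from a study of 2E, a designed macrocyclic peptide, in 5xFAD mice. This transgenic line carries human transgenes with mutations of familial Alzheimer's disease, driven by regulatory sequence of the mouse Thy1 gene, and forms amyloid deposits early in life. Polyadenylated RNA was sequenced from 71 libraries of 19 female mice aged 6 months. The animals were 5 wild-type (WT) mice given saline, 6 saline-treated 5xFAD mice and 8 5xFAD mice given 2E. Dosing with 2E began at 3 months, by intraperitoneal injection on alternate days. The dose was 5 mg/kg for 6 weeks and 2.5 mg/kg afterwards. Tissue was taken from cortex (WT n = 5, saline 5xFAD n = 6, 2E n = 8), hippocampus (n = 3, 6 and 8), brain stem (n = 4, 6 and 8) and pieces holding hippocampus and cortex together (n = 5, 5 and 7). Thus 1 animal gave up to 4 libraries and each library within a region came from a different animal. Counts over 15860 mouse genes totalled 449934 to 3842419 per library, with a median of 2265268. In these libraries 11387 to 14709 genes were detected. The 6 shallowest libraries held 449934 to 665810 counts and the other 65 held 1192473 to 3842419. Of these 6, 3 were from WT replicate 1 (cortex, hippocampus, hippocampus with cortex) and 3 from saline 5xFAD replicate 1 (brain stem, cortex, hippocampus); no 2E library was among them. A level of 3 counts corresponded to 6.67 CPM in the shallowest library and 0.781 CPM in the deepest. Reads carried no molecular identifiers, so these floors cover counting error only.

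The first question was which genes differ between 5xFAD and WT brain when both received saline. Thy1 itself, whose regulatory sequence drives the transgenes, was higher in saline-treated 5xFAD mice in all 4 regions. In cortex its log2 fold change was 1.97 ± 0.15 (SE; edgeR adjusted p = 2.08e-08, higher in 6 of 6 libraries). The change was 1.83 ± 0.23 in hippocampus (edgeR adjusted p = 0.000612, 6 of 6). It was 1.85 ± 0.15 in hippocampus with cortex (edgeR adjusted p = 1.6e-07, 5 of 5) and in brain stem 1.05 ± 0.19 (edgeR adjusted p = 0.00801). Over all libraries Thy1 lay at 999.3 to 1405 CPM in WT mice, at 1490 to 6096 CPM in saline-treated 5xFAD mice and at 2000 to 8601 CPM with 2E. No transgenic library reached down to the WT range. Reads of the human transgenes that carry Thy1 sequence would be counted with the mouse gene, and the counts cannot separate them. The mouse gene App, with a change over regions of 0.11 ± 0.11 (limma adjusted p = 0.841), did not pass the test. On GRCm38, with GENCODE vM21, Thy1 lies on chromosome 9 at 44043384 to 44048579 (plus strand, protein-coding).

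**Figure D1:**
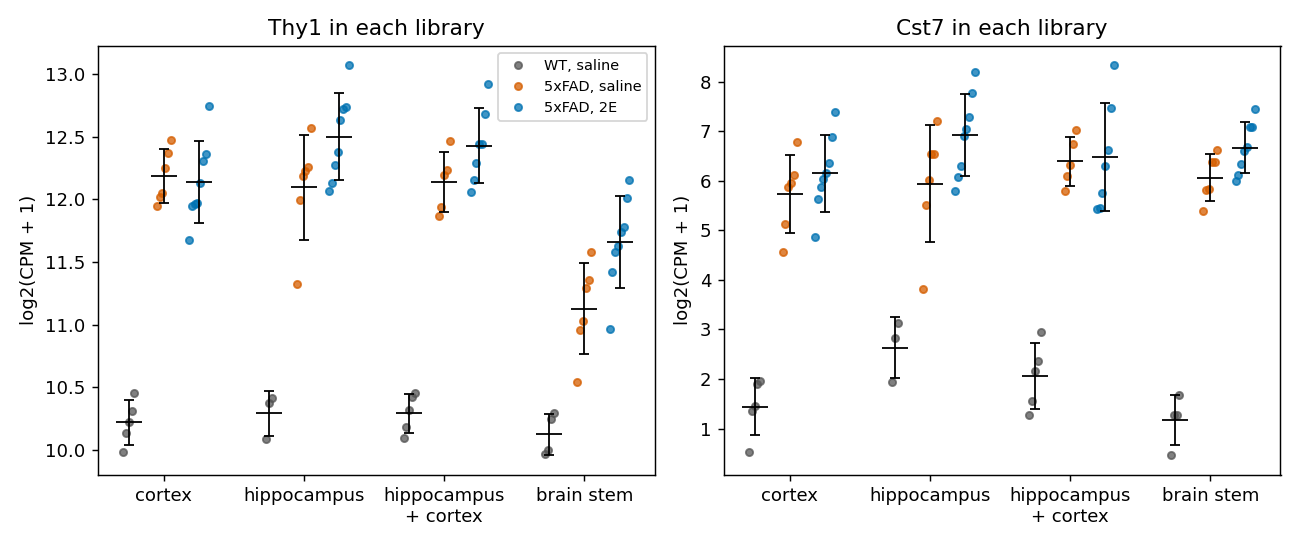
Thy1 (left) and Cst7 (right) as log2(CPM + 1) in each library, by region and group; points are libraries of different animals, long lines are group means and bars are 1 SD. In cortex Cst7 goes from 1.44 (SD 0.58, n = 5) in WT mice to 5.73 (SD 0.78, n = 6) in saline-treated 5xFAD mice and 6.15 (SD 0.77, n = 8) with 2E.

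Beyond Thy1, the regional disease genes included genes of activated microglia, lysosome and complement and the astrocyte gene Gfap, and every one was higher in 5xFAD mice. Brain stem held 23 genes past an edgeR adjusted p of 0.05, cortex 7, hippocampus 4 and hippocampus with cortex 8, with 0 lower in each. Cst7, an inhibitor of cysteine proteases and marker of disease-associated microglia, had the largest changes. They were 5.69 ± 0.44 in brain stem (edgeR adjusted p = 2.98e-09, 6 of 6 libraries) and 5.03 ± 0.57 in cortex (edgeR adjusted p = 2.23e-05, 6 of 6). WT libraries held 1 to 4 counts of Cst7 in brain stem and 1 to 6 in cortex, around the floor of 3, so the direction is clearer than the size. In hippocampus with cortex Cst7 rose by 4.47 ± 0.57 (edgeR adjusted p = 0.00033, 5 of 5). Ctsd, the lysosomal protease cathepsin D, rose by 1.44 ± 0.22 in cortex, 1.50 ± 0.27 in hippocampus and 1.25 ± 0.18 in brain stem (edgeR adjusted p = 0.00255, 0.0291 and 0.000383, each in 6 of 6 libraries). Tyrobp, the signalling adaptor of Trem2, rose by 1.78 ± 0.28 in cortex and 2.12 ± 0.38 in hippocampus (edgeR adjusted p = 0.0031 and 0.0291, 6 of 6 each). C1qb, of the first complement component, rose by 1.21 ± 0.21 in cortex (edgeR adjusted p = 0.0154, 6 of 6). The astrocyte filament gene Gfap rose by 1.55 ± 0.27 in hippocampus (edgeR adjusted p = 0.0291, 6 of 6) and 1.37 ± 0.25 in hippocampus with cortex (edgeR adjusted p = 0.0482, 5 of 5). In that tissue Npc2, a lysosomal cholesterol carrier, rose by 0.96 ± 0.17 and the transcription factor gene Nfic by 0.93 ± 0.18 (edgeR adjusted p = 0.0477 and 0.0484, 5 of 5 each). In brain stem the next genes were the microglial receptor gene Trem2 at 2.05 ± 0.27, Cd52 at 2.92 ± 0.38 and the chemokine gene Ccl6 at 3.75 ± 0.57 (edgeR adjusted p = 0.000139, 0.000142 and 0.00101, each in 6 of 6 libraries). Of the 26 different genes called in any region, Thy1 passed in all 4 and 17 passed in 1 region. The alternative tool, DESeq2, called 45 genes in cortex, 37 in hippocampus, 46 in hippocampus with cortex and 42 in brain stem. Single libraries decided part of the counts. The brain stem count was 8 without WT replicate 5 and 10 without WT replicate 2, and the cortex count 4 without WT replicate 1, 2 or 5. The hippocampus count was 1 without any of 5 single libraries, and that of hippocampus with cortex 2 without any of 7 single libraries (16 without saline 5xFAD replicate 6).

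Over the 4 regions together, with the animal kept as a block, 113 of 14586 genes passed a limma adjusted p of 0.05 between saline-treated 5xFAD and WT mice, 67 higher and 46 lower. The genes that rose were led by Thy1 at 1.60 ± 0.18 (limma adjusted p = 1.94e-08), Cst7 at 4.59 ± 0.56 (5.82e-08) and Ccl6 at 3.32 ± 0.47 (3.37e-06). C1qb rose by 1.18 ± 0.17 (limma adjusted p = 5.18e-06) and Npc2 by 0.83 ± 0.12 (1.4e-05). limma also called Tyrobp at 1.87 ± 0.29, Cd52 at 2.78 ± 0.43 (adjusted p = 2.16e-05 for both) and Ctsd at 1.32 ± 0.20 (2.54e-05). Ctsz, another cathepsin gene, was at 1.62 ± 0.27 (limma adjusted p = 7.15e-05) and Gfap at 1.32 ± 0.22 (9.52e-05). Each of these 10 genes was higher in 23 of 23 5xFAD libraries than the WT mean of its region. Scn4b, a sodium channel subunit gene abundant in striatum, rose by 1.97 ± 0.28 (limma adjusted p = 3.37e-06, 22 of 23 libraries) and Ckb, brain creatine kinase, by 0.45 ± 0.07 (limma adjusted p = 7.15e-05, 22 of 23). Neuronal genes were among those that fell. Grp, a neuropeptide gene, fell by 2.57 on the log2 scale (SE 0.43, limma adjusted p = 9.52e-05, 22 of 23). Crym, which encodes a thyroid hormone binding protein, fell by 1.67 (SE 0.29, limma adjusted p = 0.000221, 23 of 23). The hippocampal gene Fibcd1 fell by 2.24 (SE 0.44, limma adjusted p = 0.00127, 21 of 23) and Thra, a thyroid hormone receptor gene, by 0.45 (SE 0.08, limma adjusted p = 0.000118, 21 of 23). A further 7 leading genes that fell were Ccn3 (-1.80 ± 0.35), Lypd1 (-1.46 ± 0.28), Cpne7 (-1.25 ± 0.24), Atp2b4 (-1.14 ± 0.25), Icam5 (-0.81 ± 0.17), Ly6h (-0.80 ± 0.14) and Hpcal4 (-0.64 ± 0.13). They had limma adjusted p from 0.000221 to 0.00541 and 20 to 23 of 23 libraries lower. The count was 67 when each animal entered as 1 value (52 higher, 15 lower), of which 51 were among the 113. It was 78 with the striatum score of each library as a covariate (56 higher, 22 lower; 59 among the 113) and 62 without the brain stem (34 higher, 28 lower). With 1 value per animal or this covariate the genes that fell thus dropped more than those that rose. It fell to 24 without WT replicate 5, 62 without WT replicate 4, 63 without saline 5xFAD replicate 3, 67 without WT replicate 2 and 60 without the 6 libraries at unusual plate positions.

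Gene lists fixed from the labels alone were then tested with camera on the same limma fit. Disease-associated microglia genes moved together. Higher values in saline-treated 5xFAD mice were found for 27 of 28 measured members, with a median change of 1.13. In this list 13 rose (22 adjusted over the list alone, with 1 lower). Camera gave an adjusted p of 2.74e-42 for this list. The mean of its members per animal was 1.28 higher (SD 0.24 and 0.05, n = 6 and 5; exact permutation p = 0.00216, adjusted 0.0173). Of 27 lysosome genes 24 had higher values, 8 rose (17 adjusted over the list alone, with 1 lower) and the median was 0.54 (camera adjusted p = 2.1e-25). These 2 lists share 5 genes; without them the medians were 0.94 and 0.48 (camera adjusted p = 3.96e-31 and 2.32e-15). Grn, the progranulin gene, was at 0.99 ± 0.18 (limma adjusted p = 0.000616, 22 of 23). Among 12 complement genes, C1qa (0.96 ± 0.20), C1qb, C1qc (1.01 ± 0.21) and C4b (1.34 ± 0.30) rose, each in 23 of 23 libraries (limma adjusted p at most 0.00965; 6 adjusted over the list alone; camera adjusted p = 5.05e-10). The interferon list (17 of 19 higher, median 0.85) held 1 gene that rose, Ifit3 at 2.29 ± 0.58 (limma adjusted p = 0.0287, 21 of 23). MHC class I (11 of 14 higher, median 0.47) held B2m at 0.94 ± 0.17 (limma adjusted p = 0.000221, 22 of 23). Camera adjusted p was 4.05e-06 for interferon and 4.96e-05 for MHC class I. Homeostatic microglia genes had higher values in 12 of 15 (median 0.37, 0 past the test over all genes, 6 adjusted over the list alone; camera adjusted p = 2.89e-06). Alzheimer risk orthologs, a list that shares 5 genes, Trem2 and Grn among them, with other lists, had a median of 0.08 and 2 members that rose (3 adjusted over the list alone; camera adjusted p = 0.00172). Without the shared genes it did not pass (median 0.01, camera adjusted p = 0.444). Reactive astrocyte genes had a median of 0.27 with Gfap and Serpina3n (1.41 ± 0.35, limma adjusted p = 0.0216, 22 of 23) past the test. Their camera adjusted p was 0.013, and adjusted p = 0.0774 with an estimated correlation.

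Markers of tissue next to the sampled regions differed as well. Striatum markers had higher values in saline-treated 5xFAD mice in 9 of 10 genes, with a median of 1.19. Among these markers Penk (1.57 ± 0.34), Ppp1r1b (1.10 ± 0.28) and Adora2a (2.52 ± 0.66) rose (limma adjusted p = 0.00541, 0.0269 and 0.0373, in 23, 20 and 20 of 23 libraries). Adora2a lay near the floor, with a median of 0 counts in WT brain stem and 2 in WT cortex, so the size of its change is uncertain. Over the list alone 7 passed (camera adjusted p = 5.05e-10). Per animal the striatum difference was 1.01 (SD 0.88 and 0.37; exact permutation p = 0.026, adjusted 0.0909), and 1 saline-treated 5xFAD animal, replicate 2, stood at 6.14 against 3.57 to 4.73 in the other 5; without it the difference was 0.69. Oligodendrocyte and myelin genes had higher values in 15 of 16 (median 0.58, Trf rose by 0.83 ± 0.19, limma adjusted p = 0.00858, 22 of 23; 8 adjusted over the list alone; camera adjusted p = 8.71e-11). Choroid plexus and ependyma genes had higher values in 15 of 16 (median 0.88, 0 past the test, 4 adjusted over the list alone). Their camera adjusted p of 1.86e-05 became an adjusted p = 0.109 with an estimated correlation. Cortex markers (median 0.25) and hippocampus markers (median -0.44, of which Fibcd1 fell) passed camera at adjusted p = 0.0246 and 0.0014 and had adjusted p = 0.0571 and 0.0688 with an estimated correlation. Per animal cortex markers were 0.22 higher (SD 0.06 in 5xFAD and 0.09 in WT; exact permutation p = 0.00216, adjusted 0.0173) and hippocampus markers at -0.50 (p = 0.039, adjusted 0.0909). On the neuronal side, excitatory neuron and glutamatergic synapse genes had lower values in 15 of 20 (median -0.22, camera adjusted p = 0.00527, adjusted p = 0.0633 with an estimated correlation). Per animal they were at -0.16 (exact permutation p = 0.00866, adjusted 0.0462). In the inhibitory neuron list Pvalb, the parvalbumin gene, rose by 0.93 ± 0.16 (limma adjusted p = 9.52e-05, 22 of 23). The list as a whole did not pass (camera adjusted p = 0.486), its median of 0.01 and mean of -0.03 differing in sign. Of 32 lists 18 passed camera at the preset correlation, 14 up and 4 down, where random regroupings of the animals passed a median of 7. Passing camera at this setting alone is therefore weak evidence for a list. With an estimated correlation 9 held, all 9 up. Per animal, after adjustment, 4 of the 9 passed the exact test: disease-associated microglia, lysosome and complement (adjusted 0.0173 each) and Alzheimer risk orthologs (0.0277). Homeostatic microglia, interferon response, MHC class I and striatum did not (adjusted 0.0909 each), nor did oligodendrocyte and myelin (0.37 higher, SD 0.22 in 5xFAD and 0.52 in WT; exact permutation p = 0.158, adjusted 0.281; 0.56 without WT replicate 3 and 0.22 without WT replicate 4).

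**Figure D2:**
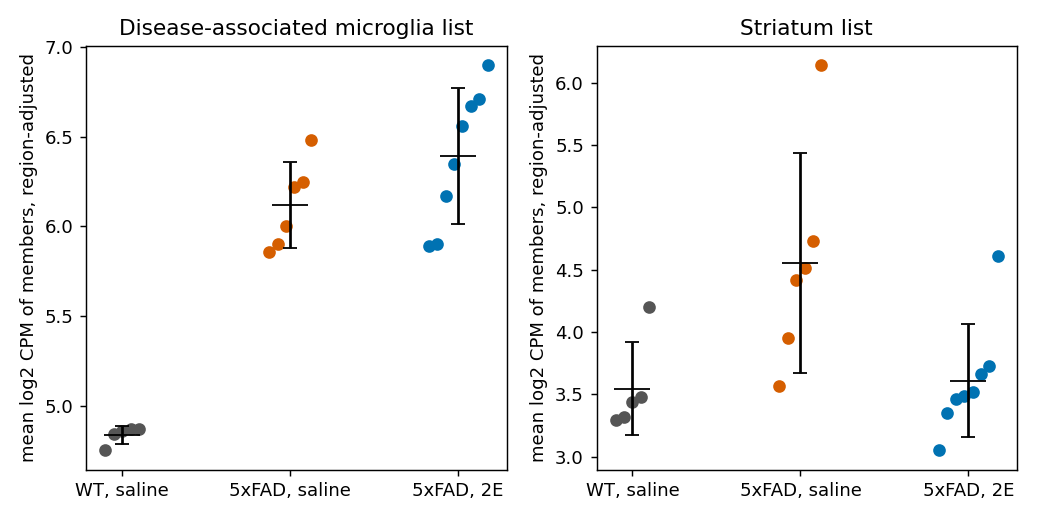
Mean log2 CPM of the disease-associated microglia list (left) and of the striatum list (right) per animal after adjustment for region; each point is 1 animal, the long line is the group mean and the bars are 1 SD. The 5 WT animals lie at 4.75 to 4.87 on the left and all 14 transgenic animals at 5.86 or above, and 1 saline-treated 5xFAD animal stands at 6.14 on the right.

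The central comparison of the study set 2E against saline in 5xFAD mice. Within single regions edgeR called 0 genes in cortex, hippocampus, hippocampus with cortex or brain stem. At an unadjusted p under 0.05 edgeR had 828, 647, 707 and 702 genes, with smallest adjusted p of 0.204, 0.814, 0.0531 and 0.0540. DESeq2 called 40, 3, 16 and 25 genes in the same order. It was not run on simulated data or on other splits, so its share of false calls is not known here. On data simulated with the same design, edgeR found 47.2% of genes changed 4-fold and 12.2% of those changed 2-fold in cortex. Changes of 2-fold were mostly out of reach within a region. Without saline 5xFAD replicate 6 the count became 6 in hippocampus with cortex and 4 in brain stem, where it was 9 without saline replicate 4 and 1 without 2E replicate 2.

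Over the 4 regions together limma called 75 genes between 2E and saline, 21 higher and 54 lower. Scn4b (chromosome 9, 45138395 to 45154152) fell by 1.39 on the log2 scale (SE 0.18, limma adjusted p = 1.36e-06), lower in 31 of 31 libraries than the saline mean of its region. Its CPM in cortex averaged 102.5 ± 61.1 (SD, n = 6) with saline, 34.7 ± 14.0 (n = 8) with 2E and 26.3 ± 19.3 (n = 5) in WT mice. Pvalb fell by 0.73 (SE 0.12, limma adjusted p = 0.000208, 29 of 31) and Rasd2, a striatal GTPase gene, by 0.97 (SE 0.16, limma adjusted p = 0.000235, 29 of 31). The opioid precursor gene Penk (chromosome 4, 4133531 to 4138819) fell by 1.40 (SE 0.25, limma adjusted p = 0.000959, 29 of 31) and Ppp1r1b, the DARPP-32 gene, by 0.92 (SE 0.21, limma adjusted p = 0.0156, 29 of 31). The other leading genes that fell were Syndig1l (-1.60 ± 0.32), Plcxd2 (-0.89 ± 0.17), Nrep (-0.65 ± 0.13), the neurofilament gene Nefm (-0.57 ± 0.12), Nfic (-0.54 ± 0.10), the mitochondrial gene mt-Nd6 (-0.50 ± 0.10), the complexin gene Cplx1 (-0.36 ± 0.07) and Ckb (-0.28 ± 0.06). They were lower in 24 to 28 of 31 libraries with limma adjusted p of at most 0.00483. Eef1a1, a translation elongation factor gene, rose by 0.40 ± 0.07 (limma adjusted p = 0.000959, 31 of 31), Ak4 by 1.00 ± 0.20 (limma adjusted p = 0.00358, 31 of 31). Cpne7 rose by 1.14 ± 0.21 (limma adjusted p = 0.0017, 30 of 31), Ly6h by 0.65 ± 0.12 (limma adjusted p = 0.00136, 29 of 31). Crym rose by 1.19 ± 0.27 (limma adjusted p = 0.0146, 28 of 31) and Thra by 0.31 ± 0.07 (limma adjusted p = 0.00671, 27 of 31). Cpne6 (0.66 ± 0.14), Camkv (0.43 ± 0.09), Galnt9 (0.76 ± 0.17), Mpped1 (0.74 ± 0.18) and Tor1a (0.80 ± 0.19) also rose. They were higher in 25 to 27 of 31 libraries with limma adjusted p of at most 0.0256. With the striatum score of each library as a covariate 9 genes were called, all 9 among the 75. With the replicate number as a block 31 genes were called (10 higher, 21 lower; 29 among the 75). limma on 1 value per animal called 0 genes (1168 at an unadjusted p under 0.05). The count over regions fell to 37 without saline 5xFAD replicate 2 or 3, and to 49 without 2E replicate 4 or 5.

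Among the gene lists, striatum markers had the smallest camera p with 2E. All 10 members had lower values, with a median of -1.07, and 2 fell (8 adjusted over the list alone; camera adjusted p = 7.21e-12, adjusted p = 0.0154 with an estimated correlation). Per animal the striatum difference was -0.94 (SD 0.46 with 2E and 0.88 with saline, n = 8 and 6; exact permutation p = 0.0137, adjusted 0.218), and -0.63 without saline 5xFAD replicate 2 (p = 0.0404). Cortex markers were the other list to hold with an estimated correlation, with a median of -0.34, 0 genes past the test (3 lower adjusted over the list alone), a camera adjusted p of 0.00827 and adjusted p = 0.0492 with an estimated correlation. Per animal cortex markers were at -0.24 (SD 0.17 with 2E and 0.06 with saline; exact permutation p = 0.00766, adjusted 0.218). Disease-associated microglia genes were not lower with 2E. Higher values were found in 22 of 28, with a median of 0.22. Ctsd (chromosome 7, 142375911 to 142388038) rose by 0.50 ± 0.12 (limma adjusted p = 0.0256, 27 of 31; 1 adjusted over the list alone). That list passed camera (adjusted p = 9.77e-06) but not with the correlation estimated (adjusted p = 0.192 with an estimated correlation). Per animal the difference was 0.28 (SD 0.38 and 0.24; exact permutation p = 0.142, adjusted 0.557). Lysosome genes had higher values in 20 of 27 (median 0.17), with Ctsd and Gaa, the acid alpha-glucosidase gene (0.31 ± 0.08, limma adjusted p = 0.0377, 25 of 31), past the test. Over the list alone 4 passed (camera adjusted p = 0.000109, adjusted p = 0.165 with an estimated correlation). Without the genes these 2 lists share, their medians with 2E were 0.17 for microglia and 0.06 for lysosome (camera adjusted p = 0.00243 and 0.0106; adjusted p = 0.265 and 0.243 with an estimated correlation). In the presynaptic list Cplx1 and Snap25 (-0.32 ± 0.07, limma adjusted p = 0.0135, 25 of 31) fell. The list had a median of -0.06, 4 lower and 1 higher adjusted over the list alone, a camera adjusted p of 0.0106 and adjusted p = 0.211 with an estimated correlation. Pvalb was the member of the inhibitory neuron list that fell (4 adjusted over the list alone; list median -0.06, camera adjusted p = 0.0109, adjusted p = 0.0985 with an estimated correlation). Of 32 lists 14 passed camera at the preset correlation, 6 up and 8 down, where random regroupings of the animals passed a median of 7. Passing camera at this setting alone is therefore weak evidence for a list. With an estimated correlation 2 held, and 4 passed fry (striatum, cortex markers, inhibitory neuron, heat shock and unfolded protein). None of the exact tests per animal passed after adjustment (smallest adjusted value 0.218).

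Whether 2E-treated 5xFAD mice differed from WT mice was asked in the same fits. Genes of microglia and lysosome and the astrocyte gene Gfap were among those above WT with 2E, in each region and over regions. Over regions Cst7 was at 5.04 ± 0.55 (limma adjusted p = 4.59e-10), Ctsd at 1.82 ± 0.19 (4.3e-10), Tyrobp at 1.96 ± 0.27 (1.01e-06) and C1qb at 1.37 ± 0.16 (5.06e-09). limma gave Ctsz at 1.93 ± 0.25 (1.49e-07), Gfap at 1.68 ± 0.20 (2.63e-08) and Thy1 at 1.89 ± 0.17 (4.5e-12). All 7 genes were higher in 31 of 31 libraries. Scn4b at 0.58 ± 0.28 (limma adjusted p = 0.595, 24 of 31) and Ckb at 0.18 ± 0.07 (limma adjusted p = 0.417, 25 of 31) did not pass. limma called 73 genes over regions, 64 higher and 9 lower. Within regions edgeR called 10 in cortex, 6 in hippocampus, 13 in hippocampus with cortex and 39 in brain stem, all higher. Tyrobp, Thy1, Gfap, Ctsd and Cst7 passed in all 4 regions. The disease-associated microglia list stood at a median of 1.49 with 18 of 28 members past the test (23 adjusted over the list alone). The lysosome list stood at 0.79 with 11 of 27 (18 adjusted over the list alone) and the complement list at 0.83 with 4 of 12 (7 adjusted over the list alone). Per animal these lists were 1.56, 0.82 and 0.86 above WT, each with an exact permutation p of 0.000777 (adjusted 0.00497), the smallest that the 1287 arrangements of 5 and 8 animals can give. Mitochondrially encoded genes had lower values in 11 of 11, with a median of -0.29. In that list 2 fell (8 adjusted over the list alone; camera adjusted p = 2.53e-10, adjusted p = 0.00689 with an estimated correlation). Striatum markers lay near the WT level with 2E, at a median of 0.13 (camera adjusted p = 0.723). The count over regions was 48 without WT replicate 5 and 116 with quality weights. The cortex count ranged from 5 to 19 and the hippocampus count from 3 to 16 as single libraries were left out, the highest without 2E replicate 2 and 2E replicate 8.

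**Figure D3:**
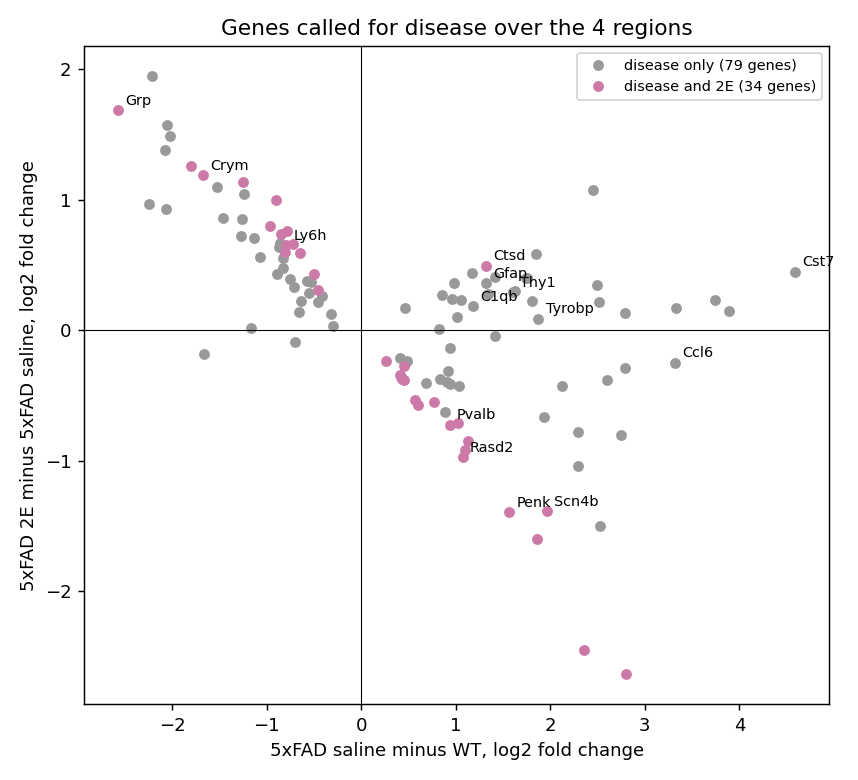
Change with disease (x axis, saline 5xFAD minus WT, log2) against change with 2E (y axis, 2E minus saline 5xFAD, log2) for the 113 genes called for disease over regions, of which 34 were also called for 2E. Both axes contain the saline-treated 5xFAD animals, which tilts such a plot downwards without any effect of 2E.

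How far the genes changed in 5xFAD moved back with 2E was summarised as the slope of the 2E change on the disease change over the 113 disease genes, with different saline-treated 5xFAD animals behind the 2 changes. The slope was -0.19 (SD 0.07 over 20 divisions of these animals), and -0.22 with all saline animals in both changes. Over the 57 disease genes at an adjusted p under 0.01 it was -0.08 (-0.19 to 0.02 over the divisions). Over the disease-associated microglia list, which was fixed from the labels, the slope was 0.15 (SD 0.06, 28 genes), so that list did not share it. Over the striatum list it was -0.82 (SD 0.50, 10 genes). With the genes chosen anew from the animals of the disease change alone the slope was -0.02 (SD 0.08). Called in opposite directions were 33 genes, and 4 with the striatum score of each library as a covariate. Of these, 19 were higher in disease and lower with 2E (among them Scn4b, Pvalb, Penk, Ppp1r1b, Rasd2, Cplx1, Nefm, Nfic and Ckb). The other 14 were lower in disease and higher with 2E (among them Crym, Thra, Ly6h, Cpne7, Grp, Icam5 and Ccn3). Independent lists of these sizes would share 0.248 and 0.0662 genes, but the 2 changes share the saline animals, so these values are no suitable reference. Regrouping the 14 transgenic animals at random gave a mean of 0.889 opposite calls and at most 18. Ctsd was the 1 gene higher in both. The score of the disease genes, those that rose minus those that fell, was -0.80 ± 0.46 (SD, n = 5) in WT mice, 1.44 ± 0.43 (n = 6) with saline and 0.64 ± 0.17 (n = 8) with 2E. The difference of -0.80 between 2E and saline had an exact permutation p of 0.000999. The genes were chosen with the same saline animals, so it is not independent evidence.

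Comparing regions within animals set out how the tissues differ. Brain stem had more of the myelin gene Mbp (1.40 ± 0.12), the matrix gene Sparc (1.75 ± 0.11), the lipid carrier gene Apod (1.30 ± 0.11), Dbi (0.86 ± 0.07) and the imprinted gene Dlk1 (6.86 ± 0.55) than cortex. It had less of the activity-regulated genes Arc (-2.24 ± 0.12), Egr1 (-2.24 ± 0.12) and Nr4a1 (-2.14 ± 0.11) and of the forebrain synaptic genes Nrgn (-1.69 ± 0.10) and Camk2n1 (-1.65 ± 0.09). Each of these held in 18 of 18 animals, with edgeR adjusted p of at most 8.82e-14, among 1763 of 11655 genes called (821 higher, 942 lower). Hippocampus differed from cortex in 245 genes (155 higher, 90 lower). Higher in hippocampus were Wipf3 (1.25 ± 0.17), Gfap (0.96 ± 0.13), Mbp (0.93 ± 0.13), the ferritin gene Fth1 (0.52 ± 0.07) and the cystatin gene Cst3 (0.33 ± 0.05). Lower were the cortical layer markers Cux2 (-1.24 ± 0.20) and Lamp5 (-1.04 ± 0.16), Mef2c (-0.75 ± 0.13), Camk2n1 (-0.74 ± 0.09) and Phf24 (-0.57 ± 0.09). Each held in 15 or 16 of 17 animals with edgeR adjusted p of at most 0.000222. Without the cortex and hippocampus libraries of 2E replicate 8, which lie apart from the others of their region, 370 genes differed.

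**Figure D4:**
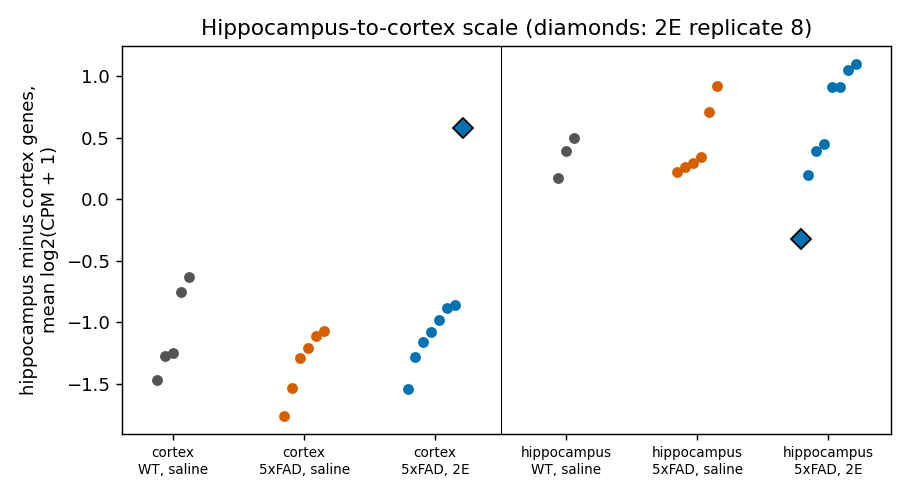
Cortex and hippocampus libraries on a scale of hippocampus genes minus cortex genes (mean log2(CPM + 1)); each point is 1 library and the diamonds are the 2 libraries of 2E replicate 8. The other cortex libraries reach at most -0.63 and the other hippocampus libraries go down to 0.17, while the diamonds lie at 0.58 (labelled cortex) and -0.32 (labelled hippocampus).

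Whether effects differ between brain stem and cortex was tested as an interaction within animals. edgeR called 0 genes for the difference in the disease effect (559 at an unadjusted p under 0.05). It called 0 for the difference in the 2E effect (650 at an unadjusted p under 0.05, smallest adjusted p = 1). No other tool was run for these. Simulated data gave 19% recovery for differences of 4-fold in the disease effect and 1.54% for 2-fold. The larger count of disease genes in brain stem than in cortex is not shown to be a difference between the regions.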

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

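The 2 tests on the libraries of 2E replicate 8, the striatum score covariate, and the way the slope and covariance were combined to judge the shared saline animals were chosen after the results were seen.

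Opposite calls in disease and with 2E, 33 genes, may reflect neighbouring tissue in saline-treated 5xFAD libraries, the shared saline animals or an effect of 2E, and the tests leave these open. The number in the position code also differed between all saline-treated 5xFAD and all 2E libraries, so the design cannot separate it from 2E. The 19 genes higher in disease and lower with 2E had a median within-group correlation of 0.273 with the striatum score (random sets -0.079 to 0.072; 0.259 for the 17 outside the striatum list), and the 14 genes in the other direction -0.098 (random sets -0.092 to 0.080), both short of the bounds set for striatal tissue. With the striatum score as covariate the median 2E change of the 19 went from -0.71 to -0.49 (median SE 0.13 in both) and of the 14 from 0.75 to 0.58 (SE 0.18 and 0.17). The median disease change of the 19 went from 0.93 to 0.53 (SE 0.17 in both) and of the 14 from -0.83 to -0.75 (SE 0.20 in both). Of the 19, 6 were still called for disease and 4 for 2E, of the 14, 8 and 1, and 4 opposite calls were left; the changes shrank while their SE stayed about level. Part of the disease change of the 19 thus goes with the striatum score and little of that of the 14, though the genes were chosen for the pattern. Penk and Ppp1r1b, among the 19, are also members of the score, which builds in part of their shrinkage. These medians were not computed for the 17 genes outside the list. With genes chosen from the animals of the disease change alone, 35 of 100 regroupings, the real one included, had a slope as low as the real one (-0.0213, mean of regroupings 0.0043), while the covariance was as low in 5 with all saline animals in both changes (-0.0576, mean -0.0456) and in 4 with disjoint animals (-0.0114, mean -0.000363). The correlations were as low in 16 (-0.507, mean -0.448) and 4 (-0.0721, mean -0.00201). On the slope alone, 35 of 100 met the bound set for the shared saline animals alone. The covariances were added to this judgement after the results were seen. With them added, the shared animals and a part beyond them cannot be told apart by these tests, and a treatment effect stays a hypothesis.

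The cortex and hippocampus libraries of 2E replicate 8 lie nearer the mean of the other region, 2 of 2, the latter by little (0.85 against 0.87). On a scale of 211 hippocampus genes minus 159 cortex genes, the library labelled cortex is at 0.58 (other cortex libraries mean -1.17, SD 0.29) and the library labelled hippocampus at -0.32 (other hippocampus libraries mean 0.55, SD 0.33). The first is within the range of the other region's libraries and the second lies between both ranges, so exchanged labels and mixed tissue cannot be told apart. On this scale 0 other cortex libraries lie as far towards hippocampus, but its genes were chosen to separate the other libraries. On the hippocampus list fixed beforehand the library labelled cortex scored 4.32 and the cortex library of WT replicate 3 scored 4.05. The library labelled hippocampus scored 3.19 and that of 2E replicate 4 scored 3.00. Ordinary variation in dissection is thus not ruled out. C1ql2, a dentate gyrus gene, is at 40.1 CPM in the library labelled cortex and 11.4 in that labelled hippocampus (medians of the others 3.51 and 56.1). Of 6 libraries whose position code, taken to be a plate position, goes with another region, 1 correlates best with the region of its position, 4 with their labelled region and 1 with neither. This 1 is the hippocampus library of 2E replicate 8, which correlates best with cortex (0.967, against 0.910 with hippocampus), as exchanged labels would give. That meets neither of the bounds set (5 of 6 either way). Where label and position differ over brain stem, the brain stem marker score (mean log2(CPM + 1)) argues against mislabelling by position. It was 4.30 and 3.88 in brain stem of WT replicate 2 and 2E replicate 8 (at most 2.65 outside brain stem). It was 1.33 and 1.48 in WT replicate 2 cortex and 2E replicate 8 hippocampus (at least 2.30 in brain stem). For hippocampus and hippocampus with cortex of WT replicate 2, mislabelling by position stays open. No biological explanation was tested.

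Disease-associated microglia genes had higher values with 2E than with saline (median 0.22). Shallow saline libraries are argued against, since the median was 0.23 without them. With the striatum score as covariate the median fell to 0.15, which met the bound set against striatal content. The score may capture tissue content only in part, so striatal content is not ruled out, and other tissue content was not tested. A chance difference between animals stays open, with an exact permutation p of 0.142 over the animals, and an effect of 2E may be present but is not shown.

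Among 88 groups and measures, 10 values, from 9 libraries, stood far from the others of their group; chance sets apart about 1 in 20 groups. Totals were apart in brain stem 2E replicate 2 (3055348 against 2021392 to 2426335 in the others), cortex WT replicate 1 (633472 against 2095089 to 2594345) and hippocampus saline 5xFAD replicate 1 (449934 against 1608101 to 2173088). The disease-associated microglia score was low in cortex of saline 5xFAD replicate 6 (5.12 against 5.40 to 5.57), the lowest of 6. The striatum score was high in hippocampus of saline 5xFAD replicate 2 (6.34 against 2.72 to 3.10), whose brain stem library had a low cortex score (3.58 against 4.18 to 4.44). In the cortex library of 2E replicate 8 the cortex score was low (4.60 against 5.00 to 5.34) and the hippocampus score high (4.32 against 2.34 to 3.02). The choroid plexus and ependyma score was high in WT replicate 3, in brain stem (4.69 against 1.51 to 1.84) and in hippocampus with cortex (2.20 against 0.80 to 1.03).

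Other splits of the animals were tested for the counts given here, not for DESeq2, the lists of 2E against WT or counts under alternatives. For disease, under 0.05 of the splits, the real one included, reached the real count. This held in cortex (7 genes, 1 of 100 splits as large, highest other 1), hippocampus (4, 1 of 84, highest other 1), hippocampus with cortex (8, 1 of 100, highest other 1) and brain stem (23, 1 of 100, highest other 7). It also held over regions (113, 1 of 100, highest other 104) and for the lists over regions (18, 2 of 100, highest other 18). Chance is thus unlikely there, but it is not excluded where another split came near or above the real count. For 2E against WT the share was also under 0.05 in cortex (10, 1 of 100, highest other 1), hippocampus (6, 1 of 100, highest other 1) and hippocampus with cortex (13, 1 of 100, highest other 5). So it was in brain stem (39, 2 of 100, highest other 64) and over regions (73, 1 of 100, highest other 61). For 2E against saline over regions the share was under 0.05 for the 75 genes (3 of 100, highest other 111) and the 33 opposite calls (1 of 100, highest other 18). It was not for the 14 lists (11 of 100, highest other 18). Chance is not excluded for the 75 genes, since other splits gave as many and 1 value per animal called none. For these genes, too, the number in the position code cannot be separated from 2E. These regroupings keep a shared group in both changes, but the slope and covariance above leave the part of the shared animals in the opposite calls open. The regional counts of 0 by edgeR are reached by 100 of 100 splits whatever the data, so splits say nothing about them (highest others 1 in cortex, 1 in hippocampus, 0 in hippocampus with cortex and 4 in brain stem; unadjusted and DESeq2 counts stand in the report). For regions the share was under 0.05 in brain stem against cortex (1763, 1 of 21, highest other 590) and hippocampus against cortex (245, 1 of 21, highest other 6). The differences of the disease effect (0, 9 of 9, highest other 0) and of the 2E effect (0, 9 of 9, highest other 0) have too few splits for a share under 0.05.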

How the results depend on the processing

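Exact tests with each animal left out, lists without shared members, the striatum score covariate, the fits without the 2E replicate 8 pair, and slopes over genes chosen from the animals of the disease change alone or without genes called lower under 2E were chosen after seeing the data. DESeq2 called more genes than edgeR: for disease 45 in cortex, 37 in hippocampus, 46 in hippocampus with cortex and 42 in brain stem; for 2E 40, 3, 16 and 25. For 2E against WT it called 36, 39 and 46 in the first 3 regions. limma with 1 value per animal gave 67 disease genes (52 higher, 15 lower) and 0 for 2E over regions (1168 at an unadjusted p under 0.05; no other tool was run on these values). Quality weights gave 116 genes for 2E against WT over regions. For disease they gave 2 in cortex, 4 in hippocampus with cortex and 0 in hippocampus (limma, 687 at an unadjusted p under 0.05, DESeq2 37). They gave 2 for 2E in hippocampus with cortex and 5 for 2E against WT in cortex. Without the libraries at unusual positions disease counts were 60 over regions, 4 in cortex, 1 in hippocampus, 2 in hippocampus with cortex and 8 in brain stem, and 2E against WT gave 6 in cortex and 10 in hippocampus. Without shallow libraries, disease gave 0 in hippocampus (edgeR, 842 at an unadjusted p under 0.05, DESeq2 37 on all libraries) and 2 in hippocampus with cortex, and 2E against WT gave 5 in cortex and 2 in hippocampus; fewer libraries enter these fits. Depth limits low genes most, since 3 counts are 6.67 CPM in the shallowest library.

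With only the 2 groups compared, hippocampus with cortex gave 19 disease genes and 1 for 2E, and cortex 6 for 2E against WT. With genes detected as a covariate disease gave 1 in hippocampus and 17 in hippocampus with cortex, and 2E against WT 10 in hippocampus. RLE size factors and the position covariate each gave 2 disease genes in hippocampus with cortex, and no low-count filter gave 14 genes for 2E against WT in hippocampus. Without the brain stem 62 disease genes were called over regions. The striatum score covariate left 9 genes for 2E and 78 for disease over regions. Without the 2E replicate 8 pair, 2E against WT gave 6 in cortex and 16 in hippocampus, and hippocampus against cortex 370. Lists that passed fell from 18 to 9 in disease and from 14 to 2 with 2E at an estimated correlation, and to 4 with 2E under fry. Without members shared with other lists the Alzheimer risk list in disease had a median of 0.01 (camera adjusted p = 0.444). The slope of -0.19 was -0.08 at adjusted p under 0.01, -0.02 with genes chosen from the animals of the disease change alone, 0.15 over the disease-associated microglia list and 0.06 over risen genes without those called lower under 2E, a choice that by itself moves the slope up, so this value supports nothing. Except where fewer libraries or genes enter, the cause was not tested.

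Replicate numbers link libraries of the same animal across regions, and the labels name no pairing of animals across groups. Over 55 pairs of same-numbered animals the correlation of deviations was -0.128 to 0.222 (median 0.012, 5 over 0.1). No animals known to be paired were there for reference, and libraries of 1 animal had an estimated correlation of only 0.0402. A pairing across groups is thus not ruled out. With the replicate number as a block 31 genes were called for 2E over regions, and no other count moved by over 1.5 times: 99 for disease and 65 for 2E against WT over regions, 8, 5, 9 and 29 for disease and 7, 5, 9 and 35 for 2E against WT in cortex, hippocampus, hippocampus with cortex and brain stem, and by edgeR 0 for 2E in each region, where 828, 647, 707 and 702 had an unadjusted p under 0.05 without the block.

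Leaving out single animals or libraries gave these ranges, with each one that moved a count by over 1.5 times. Disease over regions 24 to 146 (saline 3: 63, WT 2: 67, WT 4: 62, WT 5: 24). 2E over regions 37 to 95 (2E 4 and 5: 49, saline 2 and 3: 37). 2E against WT over regions 48 to 98 (WT 5: 48). Disease in cortex 4 to 8 (WT 1, 2 and 5: 4), in hippocampus 1 to 5 (saline 1, 3 and 4, WT 1 and 5: 1), in hippocampus with cortex 2 to 16 (saline 3, 4 and 5, WT 1, 2, 4 and 5: 2; saline 6: 16) and in brain stem 8 to 26 (WT 2: 10, WT 5: 8). 2E against WT in cortex 5 to 19 (2E 2: 19, 2E 3 and 7: 5, 2E 8: 6, WT 1: 5, WT 2, 3 and 5: 6), in hippocampus 3 to 16 (2E 8: 16, WT 1 and 5: 3, WT 2: 10), in hippocampus with cortex 8 to 20 (2E 3: 20, WT 3 and 5: 8) and in brain stem 31 to 46. 2E by edgeR 0 to 0 in cortex and in hippocampus, 0 to 6 in hippocampus with cortex (saline 6: 6) and 0 to 9 in brain stem (2E 2: 1, saline 4: 9, saline 6: 4). The slope ran from -0.23 to -0.15. For named genes 1162 values under other settings kept their direction and side of the threshold and 161 lost the threshold; for single animals or libraries left out these were 1095 and 150; for lists 442 kept, 57 lost and 11 passed anew.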

Other observations

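Immediate early genes had lower values in saline-treated 5xFAD than in WT mice in 18 of 19 (median -0.52, 0 past the limma test, 3 adjusted over the list alone; camera adjusted p = 7.86e-06, adjusted p = 0.0688 with an estimated correlation). They had higher values with 2E in 18 of 19 (median 0.44, 0 past the test, 2 adjusted over the list alone; camera adjusted p = 6.44e-06, adjusted p = 0.133 with an estimated correlation). Mitochondrially encoded genes had lower values in disease in 11 of 11 (median -0.18; camera adjusted p = 0.00462, adjusted p = 0.237 with an estimated correlation). With 2E this held in 10 of 11 (median -0.15, mt-Nd6 fell; camera adjusted p = 0.00327, adjusted p = 0.265 with an estimated correlation). Per animal neither list passed in disease (exact permutation p adjusted 0.249 and 0.0909) or with 2E (adjusted 0.443 and 0.615). Nuclear oxidative phosphorylation genes had medians of 0.08 in disease and -0.06 with 2E (camera adjusted p = 0.00534 and 0.0106; adjusted p = 0.142 and 0.265 with an estimated correlation), and cholesterol synthesis genes 0.24 in disease (camera adjusted p = 0.00789, adjusted p = 0.0571 with an estimated correlation) and -0.05 with 2E (camera adjusted p = 0.739, list direction up).

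Glial and tissue lists with 2E were as follows. Oligodendrocyte and myelin genes had lower values in 13 of 16 (median -0.21; camera adjusted p = 0.00827, adjusted p = 0.367 with an estimated correlation) and brain stem markers in 8 of 9 (median -0.45; camera adjusted p = 0.0106, adjusted p = 0.174 with an estimated correlation). Complement (median 0.18), MHC class II (0.50) and heat shock genes (0.10) passed camera upwards at adjusted p = 0.0436, 0.0472 and 0.0229, with adjusted p = 0.265, 0.335 and 0.0822 with an estimated correlation. Choroid plexus and ependyma genes had a median of -0.35 (camera adjusted p = 0.0504). Ttr, a choroid plexus transcript chosen after its values were seen, ran from 20.27 to 15270 CPM among 4 WT and from 281 to 34390 CPM among 8 2E brain stem libraries.

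Lists that did not pass camera in disease had medians of 0.23 for MHC class II (adjusted p = 0.178), 0.30 for cytokine and NF-kB (0.0581; Tlr2 rose by 2.74 ± 0.68, limma adjusted p = 0.0224, 17 of 23), 0.02 for astrocyte (0.486, mean -0.01), -0.03 for oligodendrocyte precursor (0.43, mean 0.06), -0.03 for presynaptic (0.848, mean 0.01; Cplx1 rose by 0.42 ± 0.09, limma adjusted p = 0.00375, 20 of 23, and Syn2 was at -0.41 ± 0.09, limma adjusted p = 0.00541, 22 of 23), -0.07 for heat shock (0.392), -0.03 for endothelial (0.62), -0.02 for mural (0.848), -0.19 for meningeal (0.224; Dcn at -2.07 ± 0.55, limma adjusted p = 0.0478, 22 of 23), -1.0 for blood and border immune (0.193), 0.16 for brain stem markers (0.302; Nefh rose by 1.04 ± 0.27, limma adjusted p = 0.0373, 18 of 23), 0.06 for cerebellum (0.848) and 0.32 for thalamus (0.2). With 2E the medians were 0.10 for homeostatic microglia (camera adjusted p = 0.0539), 0.23 for reactive astrocyte (0.178), -0.07 for astrocyte (0.303), -0.15 for oligodendrocyte precursor (0.692), -0.31 for interferon response (0.0845), -0.08 for MHC class I (0.94, mean 0.06), 0.05 for cytokine and NF-kB (0.831, mean -0.02), 0.02 for Alzheimer risk orthologs (0.303, mean -0.02), 0.01 for excitatory neuron (0.553), 0.15 for endothelial (0.831, mean -0.01), -0.02 for mural (0.94, mean 0.01), -0.02 for meningeal (0.692, mean 0.10), -0.35 for blood and border immune (0.347), 0.26 for hippocampus markers (0.0889), -0.20 for cerebellum (0.356) and -0.34 for thalamus (0.178).

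The GFP entry had medians of 5.30 CPM in WT, 5.71 in saline-treated 5xFAD and 5.46 in 2E libraries. Transgenic and WT animals differed by 0.04 (log2; exact permutation p = 0.808 over 11628 arrangements, n = 14 and 5), a test chosen after the values were seen. What this entry counts is not given in the sources used here.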
